A study of Homo sapiens with 3 samples.

How the data were processed

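RNA was measured by sequencing in 3 libraries of SNU-16 gastric carcinoma cells, 1 library per group. Per the labels' protocols, RNA was purified with an RNeasy Mini column kit and read on a DNBSEQ G400 instrument, and AZD4547 was given from 10 nM upward with a doubling at every other passage. The authors deposited a single table with raw read counts for 199300 annotated RefSeq transcripts of 49306 gene symbols, with the length of each transcript in bases, per the file headers. The submitters' processing notes name GRCh38, featureCounts 2.0.3, cutadapt 4.0 and SAMtools 1.17. The aligner, the annotation release and the strand setting of the counting are not given in the sources used here. The table also holds 6 columns of RPKM and TPM values, which were not used, since the counts carry the depth.

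The counts are per transcript, and not per gene as the test design had assumed. A read was counted in every transcript it overlaps: of the transcripts of genes with more than 1 transcript and at least 100 counts in D7, 78.4% lay within 10% of the highest transcript of their gene. Sums over transcripts would therefore count reads many times, and each gene was given the count of its transcript with the highest total over the 3 libraries. Symbols taken to lie at more than 1 place of the genome (3735 symbols) were left out, a step decided after the wide spread of their ratios had been seen, which left 45571 symbols. They were recognised by a repeated transcript identifier or by transcripts more than 500 rows apart in the deposited counts, and not by coordinates. Gene type and position came from a RefSeq gene table of GRCh38.p14, the same build, in which 48110 symbols (97.6%) were found, and exons of FGFR2 from a GENCODE annotation of GRCh38.

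The resulting gene counts summed to 13756117 in D7, 12451032 in D7-A and 14461702 in D7-R. Library sizes were scaled by TMM in edgeR 4.0.16 under R 4.3.3, with factors of 0.987 for D7, 1.00 for D7-A and 1.01 for D7-R. Genes with a CPM of 1 or more in at least 1 library were kept, which gave 13720 genes. The log2 ratio between libraries used CPM with a prior count of 2, and fold values of single genes were computed from CPM with no prior count. With 1 library per group there are no residual degrees of freedom, so no p-value or standard error was computed. A gene was counted as higher or lower at a ratio of 2-fold or more. Each named gene carries a 95% exact conditional binomial (Clopper-Pearson) interval on its fold, which compares the reads of the libraries and not the conditions. Shares of counts carry exact binomial intervals. Intervals, and the floor of 3 counts used where a library had 0 counts, cover counting error only, as PCR copies of a molecule are not independent.

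Before the data were examined, 47 gene lists and the rule for named genes were fixed. For each list with at least 3 detected members, the median log2 ratio was placed among the medians of 10000 random lists of the same size, matched on mean expression in 20 bins, and a list is called apart when its percentile was below 2.5 or above 97.5. This describes the libraries and is no test of conditions. The genes named are the 8 highest and 8 lowest protein-coding ratios of a comparison among genes with a CPM of 10 or more, 20 genes fixed in advance, up to 4 members of each list set apart, and up to 2 members of other lists. Other genes are said to be chosen after their values were seen, and some genes that the rule takes are not reported here. Regional differences were measured as the SD of running medians over 25 neighbouring genes, beside 1000 shuffled gene orders. The agreement of the differences from D7 was set beside simulated unchanged libraries that share D7.

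The 2-fold counts, list percentiles and chromosome medians were tested on simulated counts drawn from the real gene means and library sizes. A CV between libraries of 0.1 was assumed, independent for each gene, and the shares below hold for that CV alone. Shifts within genes and FGFR2 transcripts were not part of these simulations. For D7-A against D7, over 13720 genes, 44.3% of genes changed 2-fold, 93.8% of those changed 4-fold and 100% of those changed 8-fold were counted, beside 0.928% of unchanged genes. A planted 2-fold change lies on the threshold itself, which keeps its share low at any depth. The corresponding shares were 45.1%, 100%, 98.0% and 0.852% for D7-R against D7, and 38.7%, 98.2%, 100% and 0.920% for D7-R against D7-A. Unchanged lists were set apart in 7.5%, 4% and 4.5% of 200 draws for the same comparisons, over 13720 genes. In the step over 13458 placed genes, a log2 shift was planted on chromosome 13 and recovered at -0.28, -0.25 and -0.25. The planted shift equals the -0.27 observed for chromosome 14 in D7-R against D7. Its recovery holds for that size, and for genes that vary independently.

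Alternatives were DESeq2 1.42.0 size factors, upper quartile and total count scaling, totals without mitochondrial genes, no filter or CPM of 5 or more, prior counts of 0.5 and 5, libraries thinned to the smallest, protein-coding genes alone, a 4-fold threshold, counting intervals beyond 2-fold, list means, and windows of 15 and 50 genes. Taking the median or sum over transcripts, keeping symbols placed more than once, using genes that overlap no other and taking medians per chromosome were added after the data were seen. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used. Genes that overlap others (among those named, ACAT2, ASPH, CRYAB, ERBB2, ETV4, INSIG1, KRT8, KRT18, MALAT1, OPN3, PBLD, PLK1, RPL3, SEMA6D, TP53INP1, VIM and WDR11) are uncertain, since the strand of counting is unknown. Genes with near-identical copies, such as ADH1C, GSTA1, HSPA6, CEACAM6, GTF2H2C_2, the keratins and the ribosomal protein and mitochondrial genes, are uncertain because the treatment of reads that match several places is not given in the sources used here.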

Results

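SNU-16 is an established human gastric carcinoma cell line with amplified copies of FGFR2, a receptor tyrosine kinase for fibroblast growth factors, and of MYC. Its clone D7, clone D7 given AZD4547, an inhibitor of FGF receptor kinases, for 72 h, and a clone named D7-R#0 were profiled by RNA sequencing, and the protocols describe selection for resistance to the drug under stepwise doses. There was 1 library per group (n = 1), so none of the differences has a replicate check. The libraries are named D7, D7-A and D7-R. The sample titles give D7-A as the resistant clone and D7-R as the 72 h treatment, whereas the series text uses the name D7-R#0 for the resistant clone. Groups are therefore called by library name, and which of the pair was the treated culture is left open. Gene counts summed to 13756117 in D7, 12451032 in D7-A and 14461702 in D7-R, with counts for 18838, 20410 and 20096 genes. Mitochondrially encoded genes took 4.34% of the counts in D7 (95% exact binomial interval 4.33 to 4.35), 11.3% in D7-A (11.28 to 11.31) and 5.26% in D7-R (5.25 to 5.27).

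The first comparison asked how D7-A differed from the parental clone D7. Targets and feedback genes of the MAPK pathway, which relays FGF receptor signals, were far lower in D7-A. Of the 23 detected members of that list, 16 were at least 2-fold lower and 0 were at least 2-fold higher, and the median log2 ratio of -1.68 lay outside the -0.18 to 0.55 of expression-matched random lists. SPRY4, a feedback inhibitor of receptor signalling, was 143-fold lower (95% interval 39.2 to 1183, from 2 counts against 311). The ETS transcription factor ETV4 was 68.9-fold lower (36.1 to 151) and ETV5 32.6-fold lower (12.4 to 121). The AP-1 subunit FOSL1 was 22.7-fold lower (16.4 to 32.5), the ERK phosphatase DUSP6 20.9-fold lower (13.6 to 33.6) and CCND1, which encodes cyclin D1, 2.72-fold lower (2.59 to 2.86). In GRCh38, SPRY4 lies on chromosome 5 at 142310430 to 142325021, ETV4 on chromosome 17 at 43527846 to 43546340, ETV5 on chromosome 3 at 186046314 to 186109089 and DUSP6 on chromosome 12 at 89347235 to 89352501. Immediate early genes, which growth factors induce within minutes, had a median of -0.35, with 4 of 19 at least 2-fold lower, among them EGR1 at 3.67-fold (2.06 to 6.96) and KLF4 at 2.43-fold (2.24 to 2.65).

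Genes of proliferation, biosynthesis and protein folding were lower in D7-A as well. Of 40 detected genes of mitosis and G2/M, 11 were at least 2-fold lower (median -0.86), including the kinases PLK1 at 3.13-fold and AURKA at 2.73-fold, and the anaphase activator CDC20 at 3.03-fold. DNA replication genes had a median of -0.37 at percentile 2.45, and RRM2, a subunit of ribonucleotide reductase, was 3.35-fold lower (3.19 to 3.53). MKI67 was 1.45-fold lower (1.38 to 1.53), while the cell cycle inhibitor CDKN1A was 3.21-fold lower (2.79 to 3.69). Of 22 cholesterol synthesis genes 16 were at least 2-fold lower (median -1.39), with INSIG1 at 4.92-fold, ACAT2 at 4.50-fold and MVD at 3.69-fold. Of 17 glycolysis genes 9 were at least 2-fold lower and 1 higher (median -1.06), with the glucose transporter SLC2A1 at 2.96-fold and PKM at 2.91-fold. Of 22 genes of the ATF4 and amino acid response 11 were lower and 0 higher (median -0.99). Its glutathione-degrading enzyme CHAC1 was 11.3-fold lower (6.68 to 20.6) and the cystine transporter SLC7A11 3.74-fold lower (3.33 to 4.23). Heat shock genes had a median of -1.15 (8 of 13 lower, HSPH1 at 3.95-fold), genes of the unfolded protein response -0.74 (5 of 19 lower, SDF2L1 at 3.40-fold) and MYC targets and ribosome biogenesis genes -0.62 (7 of 36 lower, ODC1 at 2.97-fold), while MYC itself was 1.06-fold higher (1.03 to 1.08). NF-kB targets had a median of -0.38, with the antimicrobial protein gene LCN2 at 4.53-fold lower (2.58 to 8.49).

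Other genes were higher in D7-A. Receptor tyrosine kinases other than the FGF receptors had a median of 0.86, with 8 of 19 at least 2-fold higher and 1 lower. ERBB2 (chromosome 17, 39688094 to 39728658) was 3.14-fold higher (2.92 to 3.38) and its partner ERBB3 2.62-fold higher (2.52 to 2.71), while EGFR was 1.14-fold higher (1.06 to 1.22) and MET 1.02-fold lower (0.975 to 1.07). In every library EGFR was counted on a transcript of 48454 bases, and whether it takes in intronic reads was not tested. FGFR3 was 3.45-fold higher (2.78 to 4.31), FGFR2 1.48-fold higher (1.46 to 1.5) and FGFR4 1.36-fold lower (1.21 to 1.54). FGFR1 and the receptor gene AXL had 0 counts in all 3 libraries. Neuroendocrine and neuronal genes had a median of 1.42, with 9 of 13 higher and 0 lower, led by the prohormone convertase PCSK2 at 29.4-fold (14 to 74.2) and the granin SCG2 at 9.46-fold (6.24 to 14.9). The RAS, RAF and PI3K pathway list had a median of 0.13, with 30 of 31 members within 2-fold and 1, TSC1, at 2.01-fold higher (1.74 to 2.34).

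RNA classes that vary with RNA quality and cell state differed along with these groups. Mitochondrially encoded transcripts had a median of 1.35 in D7-A against D7, with 10 of 13 at least 2-fold higher and COX1 at 3.01-fold. Nuclear-retained and small structural RNAs had a median of 0.44, with RN7SK at 6.16-fold (5.17 to 7.38) and MALAT1 at 4.56-fold (4.42 to 4.69). Cytosolic ribosomal protein genes had a median of 0.57, of which 1 of 46, RPL3, was beyond 2-fold at 2.09 (2.05 to 2.12).

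Among single genes of CPM 10 or more, ADH1C, an alcohol dehydrogenase of the gut and liver, differed most. It was 313-fold higher in D7-A (55.7 to 12398), from 287 counts against 1. The scaffold protein gene PDZK1 was 48.9-fold higher (22.2 to 134), PBLD 35.1-fold (18.2 to 77.6), the intestinal transcription factor ISX 34.7-fold (21.2 to 61.2), the fatty acid transporter CD36 29.1-fold (15.1 to 64.3), SEMA6D 28.1-fold (11.7 to 88.1) and the brush border peptidase ANPEP 25.2-fold (12.5 to 59.3). Besides SPRY4, ETV4, ETV5 and FOSL1, the lowest were MYEOV at 106-fold (41.0 to 390), the gastric marker ANXA10 at 45.0-fold (20.4 to 124), the adhesion molecule CEACAM6 at 33.8-fold (28.3 to 40.7) and the collagenase MMP1 at 25.3-fold (13.6 to 53.4). The intestinal lineage list that holds ISX and CEACAM6 was not set apart (4 higher, 7 lower of 23), nor were epithelial genes, although KRT18 was 6.65-fold lower and KRT8 3.42-fold lower. CDH1 was 1.46-fold higher (1.40 to 1.52). Mesenchymal genes were not set apart either (1 higher, 3 lower of 10).

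In all, 2212 genes were at least 2-fold higher and 724 lower in D7-A among 13720 tested, with a median log2 ratio of 0.08. Of 45 lists, 6 were apart on the high side and 11 on the low side, where the percentile limits alone give 2.25 and 7.5% of simulated unchanged lists were apart. With CPM of 5 or more, 1251 genes were higher, and 1060 were higher with the whole counting interval beyond 2-fold. At least 1 alternative ended the calls of the replication, immediate early, other receptor kinase, nuclear RNA and RAS, RAF and PI3K lists.

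**Figure D1:**
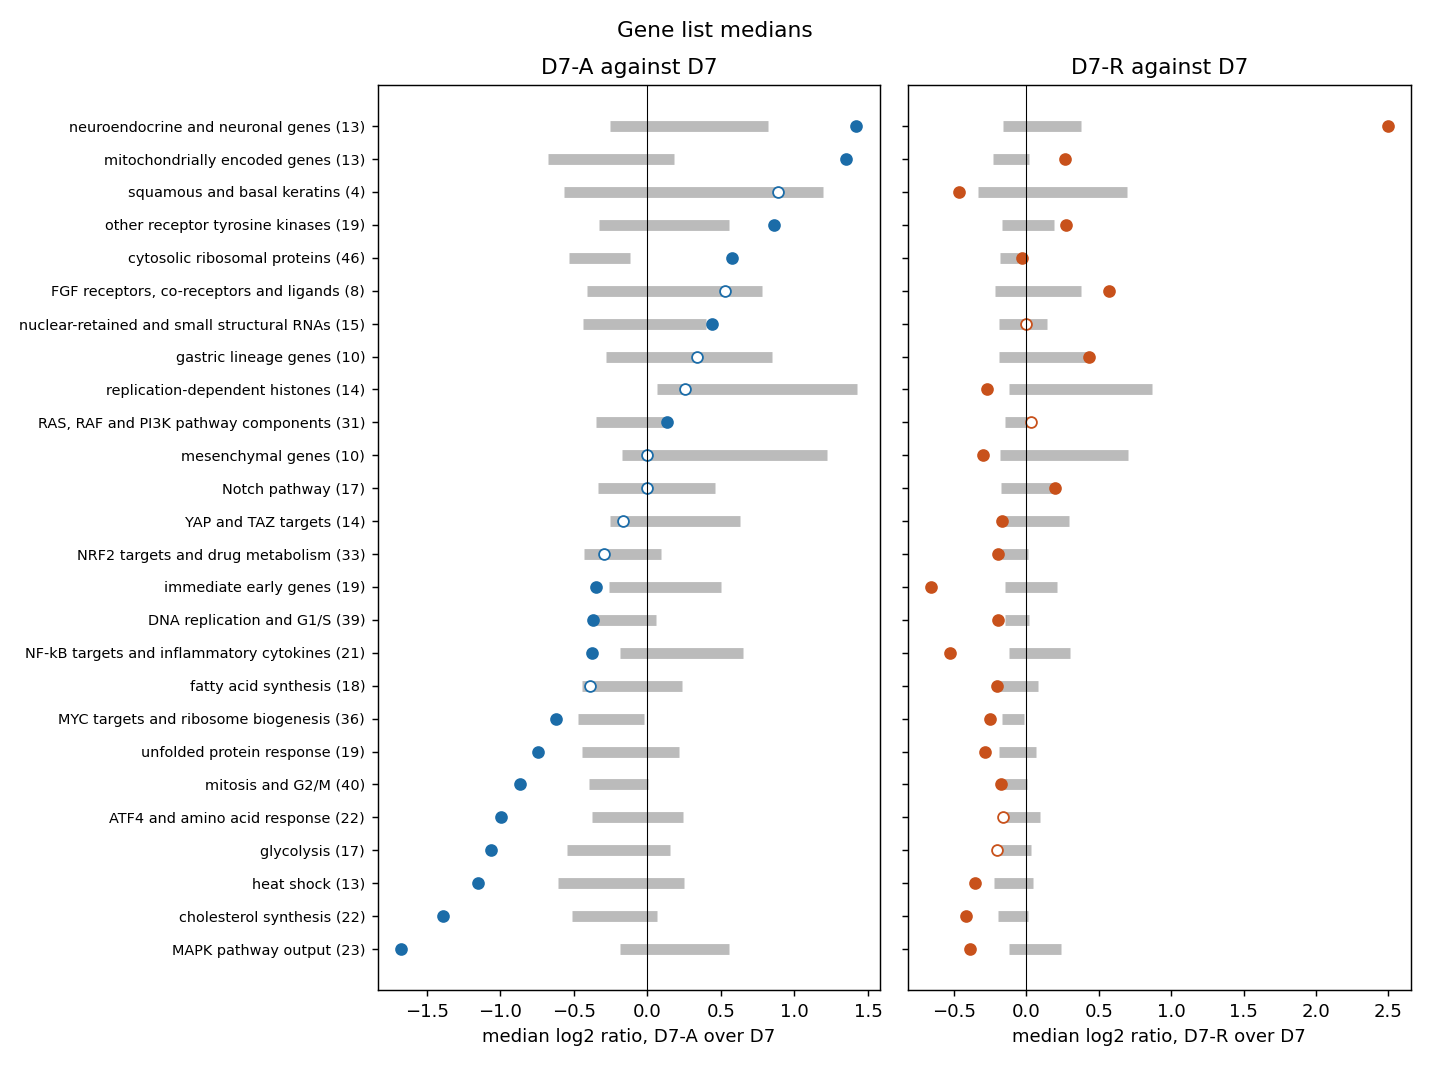
Median log2 ratio against D7 (x axis) of the gene lists set apart in at least 1 comparison with D7, with the number of detected members in brackets; grey bars span the central 95% of expression-matched random lists and filled points lie outside them. In D7-A the MAPK list has the lowest median of those shown (-1.68), and in D7-R the neuroendocrine list has the highest (2.5).

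The second comparison asked how D7-R differed from D7. FGFR2 (chromosome 10, 121478330 to 121598458) was 4.26-fold higher in D7-R (4.21 to 4.31), at 9759 CPM against 2292, the fold of its transcript XM_017015921.3. MAPK targets differed less from D7 than in D7-A: their median was -0.39, outside the -0.12 to 0.24 of random lists, with 5 of 23 at least 2-fold lower and 3 higher. SPRY4 stood at 19.6 CPM against 22.9 (log2 ratio -0.23), DUSP6 was 1.15-fold lower (1.01 to 1.31), ETV5 1.01-fold lower (0.797 to 1.28), ETV4 1.41-fold lower (1.26 to 1.58) and CCND1 1.33-fold lower (1.28 to 1.38). The members furthest below D7 were EGR1 at 16.2-fold (6.01 to 61.4), FOS at 6.82-fold (4.68 to 10.2), DUSP5 at 3.32-fold (2.57 to 4.34) and FOSL1 at 3.10-fold (2.73 to 3.53). EGR1 and FOS also belong to the immediate early genes, which had a median of -0.66 with 5 of 19 lower and 0 higher, led by FOSB at 18.1-fold (7.48 to 57.3). NF-kB targets had a median of -0.53, with LCN2 at 20-fold lower (7.48 to 75.3) and the chemokine CXCL5 at 4.24-fold lower (2.95 to 6.22).

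The fold of FGFR2 depended on the transcript counted, which was examined after the values were seen. The transcript NM_001144913.1, which has an alternative last exon, was 6.15-fold higher (6.06 to 6.24) and NM_001144919.2, with the same exon, 6.19-fold higher (6.10 to 6.28), while NM_022970.3, which has the canonical last exon, was 4.26-fold higher (4.20 to 4.31). NM_001320654.2, which has the canonical last exon but another first exon, was 3.56-fold higher (3.51 to 3.61), so the fold also varied with the 5' end. In D7-A it was 1.46-fold higher, and the other transcripts named here were each 1.48-fold higher. The difference between the counts of NM_022970 and NM_001144913 was 34.0% of the NM_022970 count in D7 (33.5 to 34.6, exact binomial interval), 34.1% in D7-A (33.6 to 34.5) and 4.65% in D7-R (4.55 to 4.77). On chromosome 10 of GRCh38 the alternative last exon spans 121481835 to 121482177 and the canonical one 121478334 to 121480021, of which part encodes the receptor's C-terminal tail. Reads of these transcripts overlap upstream of the last exon, and NM_001144913 also differs from NM_022970 at the 5' end. The reads of each last exon were therefore not measured singly, and the 4.65% includes 5' reads. NM_001144919 shares the first exon region of NM_022970. Its counts were 21078 in D7, 28535 in D7-A and 140872 in D7-R, against 31088, 42138 and 142934 for NM_022970. WDR11, the gene next to FGFR2, had a log2 ratio of -0.35 in D7-R against D7 and 0.76 in D7-A against D7.

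**Figure D2:**
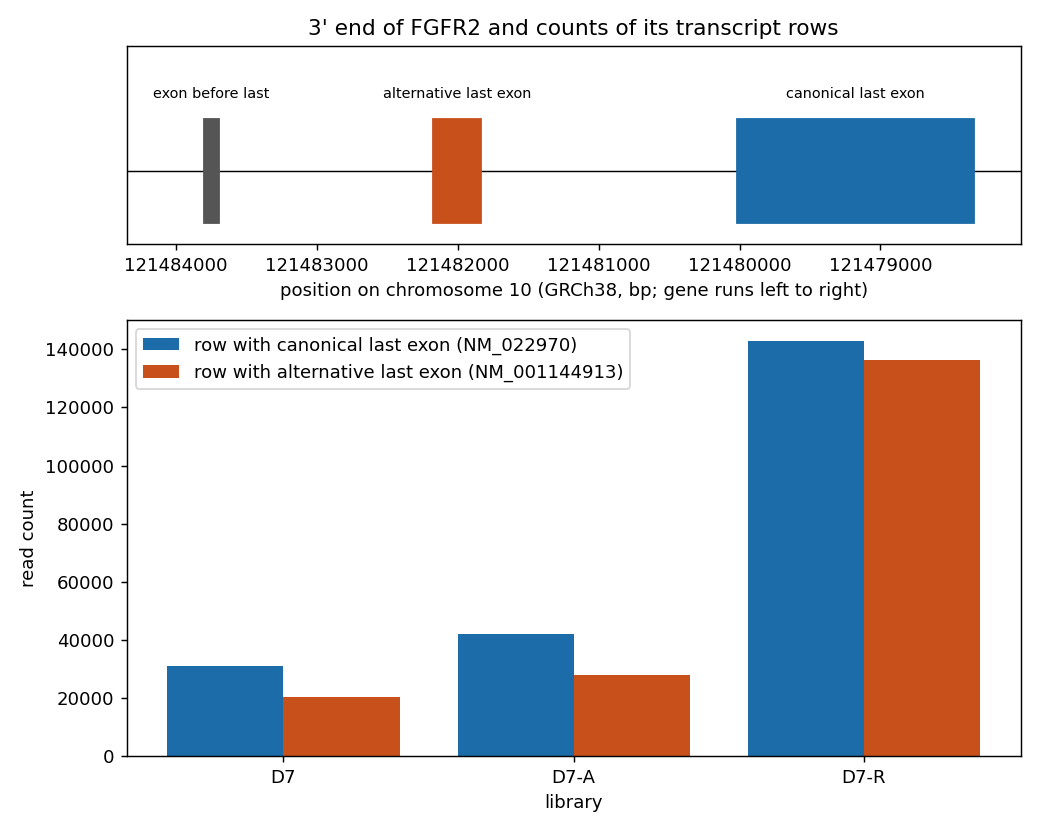
Top, the 3' end of FGFR2 on chromosome 10 (GRCh38, base pairs), drawn to scale in the direction of transcription; bottom, read counts (y axis, from 0) of a transcript with the canonical and one with the alternative last exon in the 3 libraries. The counts differ by 34.0% of the canonical transcript's count in D7, by 34.1% in D7-A and by 4.65% in D7-R.

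Neuroendocrine and neuronal genes were higher in D7-R than in D7, with a median of 2.5 and 10 of 13 at least 2-fold higher. The granins CHGB (chromosome 20, 5911510 to 5925353), SCG2 and SCG3 were 33.7-fold (16.1 to 84.7), 27.1-fold (18.2 to 42.2) and 13.8-fold (10.3 to 18.9) higher. Among the largest single differences were also the neuronal protein genes CRMP1 at 68.5-fold (18.6 to 571) and SYT13 at 18.9-fold (12.5 to 29.7), the disaccharidase SI at 92.6-fold (25.3 to 770), the cationic amino acid transporter SLC7A2 at 27.2-fold (12.2 to 75), RGS4 at 22.5-fold (13.4 to 40.6) and the gastric claudin CLDN18 at 21.4-fold (10.2 to 54.1). Gastric lineage genes had a median of 0.43 with 4 of 10 higher and 1 lower. The list of FGF receptors, co-receptors and other FGF family genes had a median of 0.57 with 3 of 8 higher and 1 lower. Those higher were FGFR2, FGF13 at 4.30-fold (2.90 to 6.56) and FGF14 at 45.1-fold (15.1 to 221, from 146 counts against 3). Whether the products of FGF13 and FGF14 act on FGF receptors was not examined. Other receptor tyrosine kinases had a median of 0.28 with 5 of 19 higher, including EPHB2 at no less than 17.3-fold (56 counts against 0) and PTK7 at 11.4-fold (5.80 to 25.6), while ERBB2 was 1.1-fold (1.01 to 1.2) and ERBB3 1.21-fold higher (1.16 to 1.26). EGFR was 1.00-fold lower (0.938 to 1.07) and MET 1.08-fold lower (1.04 to 1.13). Notch pathway genes had a median of 0.20 with 4 of 17 higher, among them the ligand DLL3 at 5.17-fold (3.07 to 9.25).

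Several lists that were lower in D7-A also lay below their random range in D7-R, with smaller medians and no member beyond 2-fold in most. The medians were -0.42 for cholesterol synthesis, -0.28 for the unfolded protein response, -0.25 for MYC targets, -0.19 for DNA replication and -0.17 for mitosis, each with 0 members at least 2-fold lower. MKI67 was 1.02-fold lower (0.972 to 1.06). Heat shock genes had a median of -0.35 with 1 of 13 beyond 2-fold, CRYAB at no less than 9.72-fold lower (0 counts against 27). HSPA6, a stress-induced chaperone, was 44.1-fold lower (18.6 to 137). Other lists, fatty acid synthesis and squamous and basal keratins among them, lay below their random range in D7-R but were not set apart in D7-A. NRF2 targets had a median of -0.19 (1 higher, 0 lower of 33) and mesenchymal genes -0.30 (1 higher, 3 lower of 10). YAP and TAZ targets had one of -0.17 (2 higher, 3 lower of 14), with CCN1 at 2.90-fold lower (1.95 to 4.41). Replication-dependent histones had one of -0.27 (1 higher, 2 lower of 14). Fatty acid synthesis genes had a median of -0.20 and a mean of 0.093, and the 4 detected squamous and basal keratins a median of -0.46 and a mean of 0.19, so that median and mean differ in sign. Mitochondrially encoded genes had a median of 0.27, with COX1 at 1.29-fold higher, and cytosolic ribosomal protein genes one of -0.03, which lay above their random range of -0.18 to -0.06 and was 0.012 with total count scaling. Further genes among the lowest were GTF2H2C_2 at 12.2-fold (6.93 to 23.5), the carbonic anhydrase CA2 at 5.08-fold (4.08 to 6.37), AADAC at 4.75-fold and the glutamine transporter SLC38A5 at 4.57-fold.

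In all, 1067 genes were at least 2-fold higher and 181 lower in D7-R among 13720 tested (median log2 ratio 0.01), and 7 lists were apart on the high side and 15 on the low side of 45, where the percentile limits alone give 2.25 and 4% of simulated unchanged lists were apart. With CPM of 5 or more, 446 genes were higher and 86 lower, and 462 and 55 had the whole counting interval beyond 2-fold. At least 1 alternative ended or turned the calls of the gastric, Notch, fatty acid, YAP and TAZ, squamous keratin and histone lists. For cytosolic ribosomal proteins the median changed sign with total count scaling and with CPM of 5 or more. Their percentiles there, 99.73 and 99.54, stayed above the limit.

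**Figure D3:**
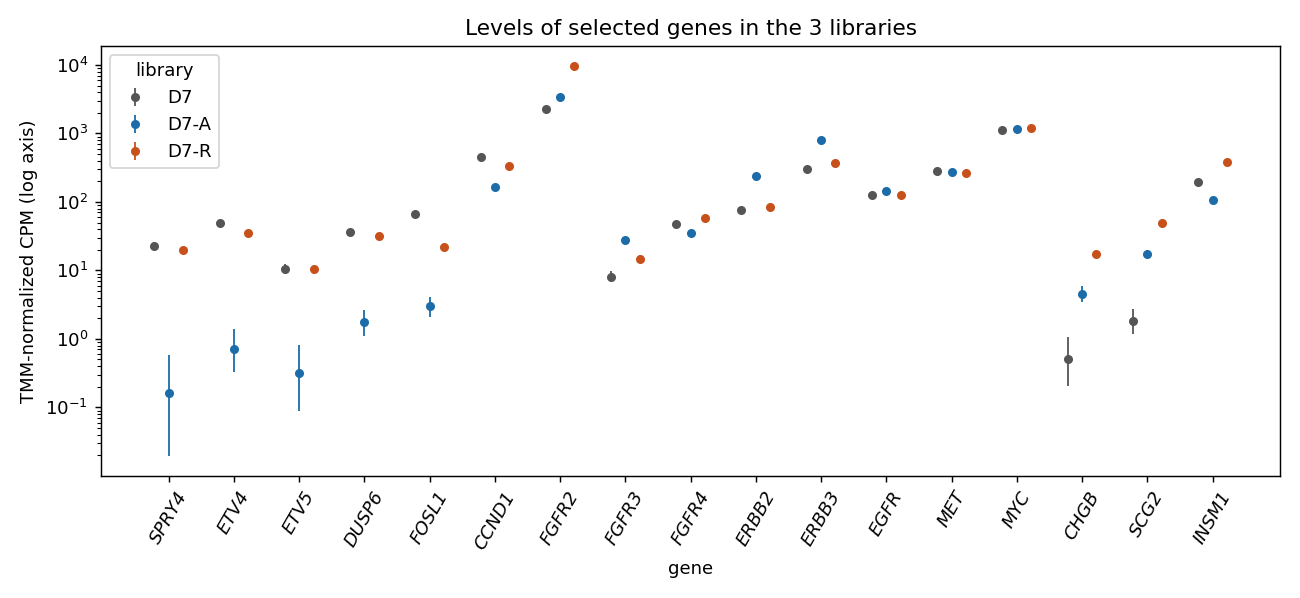
TMM-normalized CPM (log axis) of selected genes in the 3 libraries, with 95% Poisson intervals for counting error. SPRY4, ETV4, ETV5 and DUSP6 are low in D7-A alone, while FGFR2 reaches 9759 CPM in D7-R against 2292 in D7.

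The third comparison set D7-R against D7-A, the libraries that the titles and the names describe differently. MAPK targets were higher in D7-R, with a median of 1.44 and 16 of 23 genes at least 2-fold higher and 2 lower. SPRY4 was 122-fold higher (33.4 to 1011), ETV4 48.9-fold (25.6 to 108), ETV5 32.3-fold (12.3 to 120) and DUSP6 18.1-fold (11.8 to 29.2). FGFR2 was 2.88-fold higher (2.84 to 2.91), whereas ERBB2 was 2.86-fold lower (2.67 to 3.06), ERBB3 2.16-fold lower (2.09 to 2.23) and FGFR3 1.89-fold lower (1.59 to 2.25). Neuroendocrine genes had a median of 1.08 with 9 of 13 higher, including the neuronal tubulin TUBB3 at 4.58-fold (4.04 to 5.21) and the transcription factor INSM1 at 3.57-fold (3.37 to 3.79), and the neuropeptide precursor VGF was 26-fold higher (17 to 41.8). Gastric lineage genes had a median of 1.27 with 6 of 10 higher, such as ANXA10 at 11-fold (4.85 to 31.0) and SOX2 at 2.78-fold (2.41 to 3.22).

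Biosynthetic and stress lists were higher in D7-R than in D7-A. Medians were 1.06 for the ATF4 and amino acid response (12 of 22 higher, CHAC1 at 9.17-fold), 0.97 for cholesterol synthesis (11 of 22, ACAT2 at 3.68-fold), 0.80 for heat shock (3 of 13 higher, 1 lower), 0.72 for glycolysis (3 of 17, HK1 at 2.34-fold), 0.68 for mitosis (4 of 40, PLK1 at 2.25-fold), 0.48 for fatty acid synthesis (5 of 18, ACLY at 3.06-fold), 0.43 for the unfolded protein response (3 of 19) and 0.38 for MYC targets (3 of 36, ODC1 at 2.40-fold). Mitochondrially encoded genes were lower, with a median of -1.06 and 10 of 13 at least 2-fold lower, as were nuclear-retained and small structural RNAs (-0.92, 7 of 15, MALAT1 at 3.67-fold) and cytosolic ribosomal protein genes (-0.55, 0 of 46). Interferon-stimulated genes had a median of -0.42 with 6 of 24 lower, among them DDX60 at 3.45-fold (2.62 to 4.59). Among single genes, ADH1C was 84.5-fold lower (32.6 to 312), HSPA6 32.3-fold (13.5 to 101), the glutathione transferase GSTA1 27.2-fold (14.5 to 57.5), the fibrinogen chain FGB 22.4-fold (17.4 to 29.1), PDZK1 19.8-fold (12 to 35.1) and CD36 18.8-fold (11.2 to 34.2), while MYEOV was 44.6-fold higher (17.2 to 165), SLC7A2 18.7-fold (9.28 to 44.0) and CCN3 14-fold (8.81 to 23.6). In all, 590 genes were at least 2-fold higher and 1139 lower among 13720, and 12 lists were apart on the high side and 6 on the low side of 45. With CPM of 5 or more, 341 were higher and 612 lower. The intestinal lineage list was apart at -0.24, but its mean was 0.29, and its call and those of the epithelial (-0.10) and interferon lists ended or turned under at least 1 alternative.

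Genes of chromosome 14 were lower together in D7-R. Their median log2 ratio was -0.27 against D7, with 73.8% of 413 genes below 0, and -0.30 against D7-A, with 73.1% below 0. In 1000 shuffled gene orders the chromosome 14 median against D7 stayed between -0.06 and 0.08. The other chromosomes had medians of -0.04 to 0.10 in D7-R against D7, and of these chromosome 22 (0.10, 371 genes) also lay beyond every shuffled order. In D7-A against D7 no chromosome did, and chromosome 14 had a median of 0.12. Chromosome 22 had a median of 0.11 there, inside a wider shuffled range of -0.08 to 0.28. In D7-R against D7-A the chromosome 22 median was 0.04, inside -0.11 to 0.11, so it did not set these libraries apart. The SD of running medians over 25 neighbouring genes was 0.217 in D7-A against D7 (shuffled mean 0.187), 0.107 in D7-R against D7 (0.0826) and 0.164 in D7-R against D7-A (0.132), above every shuffled order in each comparison. The median per chromosome was examined after the running medians had been seen, and chromosome 14 was singled out from its values.

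**Figure D4:**
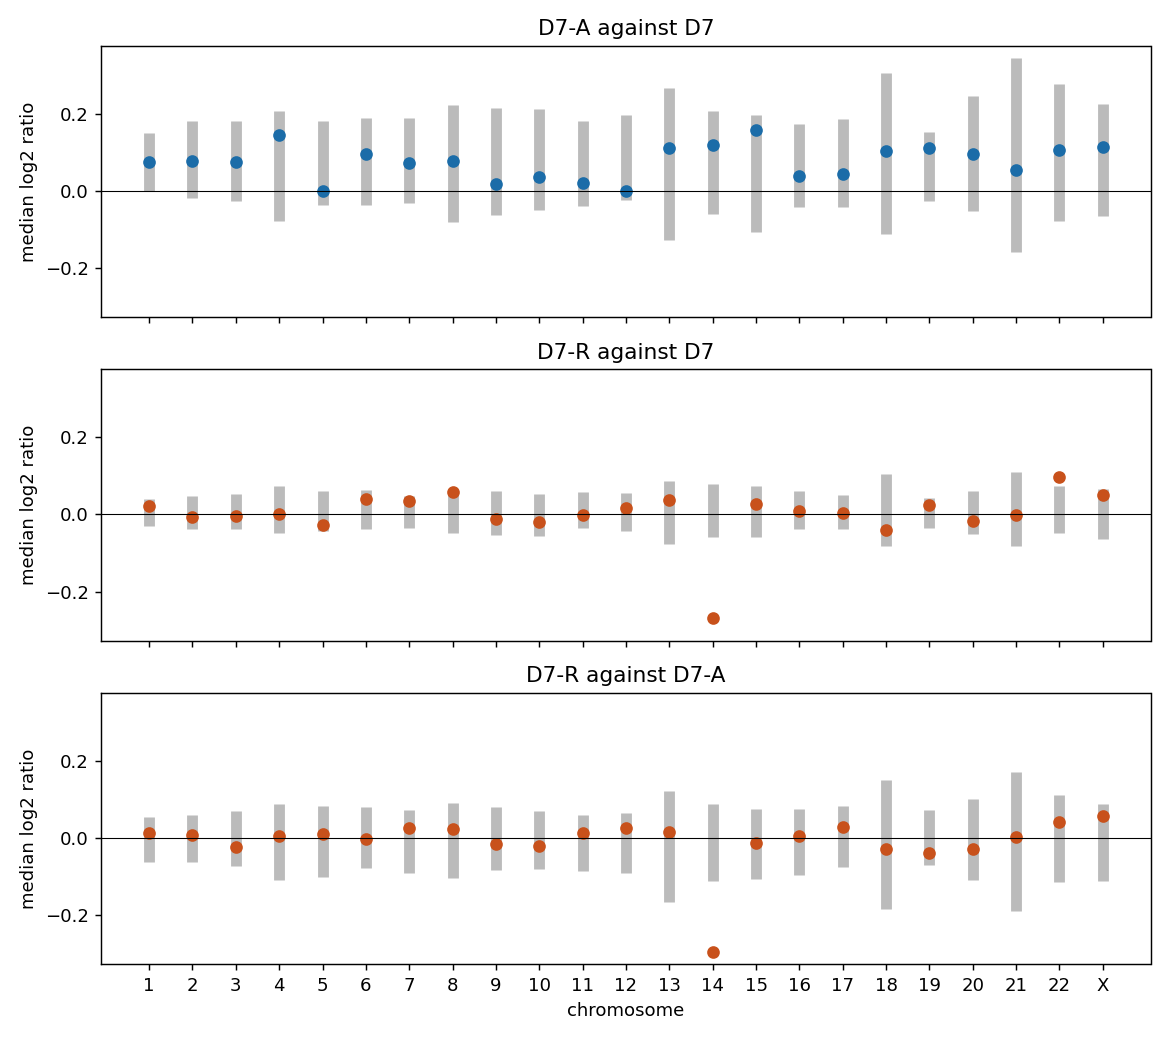
Median log2 ratio of the tested genes of each chromosome (points) in the 3 comparisons, with grey bars from the lowest to the highest of 1000 shuffled gene orders. Chromosome 14 lies at -0.27 in D7-R against D7 and at -0.30 in D7-R against D7-A.

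The differences of D7-A and D7-R from D7 ran partly in parallel. Of the genes at least 2-fold from D7 in both, 819 were higher in both, 70 lower in both and 15 opposite, where independent lists give 172 and 9.55. Simulated unchanged libraries that share D7 gave 27.5, 35.2 and 82.5 genes higher in both and 16.1, 18.2 and 40.5 lower in both for an assumed CV between libraries of 0, 0.1 and 0.2. The Pearson correlation of the log2 ratios was 0.625 across 13720 genes, which are not independent replicates. Both ratios share the D7 library, and simulated unchanged libraries gave 0.496 to 0.501 when the assumed CV between libraries was 0 to 0.2. The covariance was 0.398, against 0.0347, 0.0543 and 0.115 simulated for a CV of 0, 0.1 and 0.2. The single D7 library cannot be split into libraries, so part of the excess may come from the shared control. With its counts split at random into 2 equal parts, which removes shared counting error alone, the correlation was 0.540.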

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

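The look at genes placed more than once was chosen after their ratios had been seen. Symbols taken to lie at more than 1 place of the genome enter none of the comparisons, and their counts are given here because they lie outside the main measurement. They took 0.748% of all gene counts in D7 (95% exact binomial interval 0.744 to 0.753; 103685 counts, 1083 genes), 0.698% in D7-A (0.694 to 0.703; 87579 counts, 1155 genes) and 0.751% in D7-R (0.747 to 0.755; 109428 counts, 1147 genes). With 1 library per group no share could be set against a spread between replicates.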

How the results depend on the processing

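The median or sum over transcripts, symbols placed more than once, genes overlapping no other and medians per chromosome were chosen after the results were seen. Counts are given for D7-A against D7 (higher, lower), then D7-R against D7, then D7-R against D7-A. Without a filter they were 3696 and 1529, 1823 and 778, and 1121 and 2238, since genes of few counts enter. With CPM of 5 or more they were 1251 and 486, 446 and 86, and 341 and 612, since such genes leave. With the whole counting interval beyond 2-fold they were 1060 and 382, 462 and 55, and 269 and 440. At a 4-fold threshold they were 673 and 94, 376 and 30, and 128 and 218. Genes lower in D7-R than in D7-A numbered 722 for protein-coding genes, 751 for sums over transcripts and 744 for genes overlapping no other. Keeping symbols placed more than once gave 280 genes lower in D7-R than in D7. All other alternatives, the scalings among them, stayed within 1.5 times of the values in the report. The median of all genes moved most with upper quartile scaling, from 0.08 to 0.17 in D7-A against D7. The correlation of the differences from D7 was 0.679 with sums over transcripts and 0.540 with D7 split into 2 parts.

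For D7-R against D7, the mean in place of the median was 0.093 for fatty acid synthesis and 0.19 for squamous keratins. Cytosolic ribosomal proteins had a median of 0.012 with total count scaling and 1.08e-05 with CPM of 5 or more. Histones had medians of 0.49 with CPM of 5 or more and 0.53 with sums over transcripts. For D7-R against D7-A, intestinal genes had a mean of 0.29, and a median of 0.10 with symbols placed more than once kept. Except where fewer or more genes enter, the cause was not tested. List by list over all alternatives, 428 values for D7-A against D7 kept their call, apart or not, 9 crossed to apart and 9 crossed back. For D7-R against D7 these were 417, 8 and 15, with 6 reversed, and for D7-R against D7-A 429, 8 and 7, with 2 reversed. Direction was checked only for lists set apart, so other lists could change sign and still count as kept. Gastric lineage genes in D7-A against D7, not set apart, had a median of 0.34 and a mean of -0.09. Among named genes 1306 values stayed on their side of 2-fold and 5 (of VIM and CCND1) fell inside it. The number of lists apart stayed within 1.5 times, and the regional SD stayed above every shuffled order, under each alternative run for them. No paired analysis was possible because each group has 1 library. Depth limits the precision of genes of few counts: the 143-fold ratio of SPRY4 in D7-A, from 2 counts against 311, has an interval of 39.2 to 1183.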

Other observations

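The comparison of regional spread between D7-A and D7-R was planned before the data were examined; the tests on the MAPK list as a mark of inhibition, on the ratio of regional spreads, on chromosome 14, on FGFR2 and on shifts within genes were chosen after the results had been seen. Several genes whose ratios to D7 have not been given so far differed from D7. The pro-apoptotic gene BMF was 7.83-fold higher in D7-A (6.10 to 10.2) and 2.62-fold higher in D7-R (1.99 to 3.49), and HRK, of the same BH3 family, no less than 19.4-fold higher in D7-R (63 counts against 0). CYP1A1, an aryl hydrocarbon receptor target, was 22-fold higher in D7-A (13.1 to 39.8) and GSTA1 21-fold higher (11.8 to 41.2). The p53-inducible gene TP53INP1 was 5.43-fold higher in D7-A (4.19 to 7.13) and 5.26-fold higher in D7-R (4.07 to 6.89). The PARP family gene PARP14 was 6.35-fold higher in D7-A (3.77 to 11.3) and 5.94-fold higher in D7-R (3.54 to 10.6). NOTCH3 was 5.95-fold higher in D7-A (3.10 to 12.5) and 3.87-fold higher in D7-R (1.98 to 8.29). CD74, the class II invariant chain, had 1 count in D7, 16 in D7-A and 59 in D7-R. These are single genes of large ratio. The p53 target list was not set apart in D7-A (4 higher, 6 lower of 21) or D7-R (2 higher, 1 lower). The BCL2 family and apoptosis list was not set apart in D7-A (5 higher, 1 lower of 29) or D7-R (2 higher, 0 lower). NRF2 targets and drug metabolism genes were not set apart in D7-A (4 higher, 8 lower of 33). Drug efflux genes of the ABC family were not set apart in any comparison, with medians of -0.06 in D7-A and -0.02 in D7-R over 11 detected members.

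Genes of low level made up most of those higher in D7-A. Of 5 groups of mean expression, the lowest had 43.2% of 2744 genes at least 2-fold higher in D7-A than in D7 and the highest 2.55%. In D7-R the shares were 25.7% and 0.401%. The direction turned with level in D7-A against D7. There 1186 genes were at least 2-fold higher and 167 lower in the lowest group, but 70 higher and 213 lower in the highest. The group next to the highest had 105 and 115. Long noncoding RNA genes had a median log2 ratio of 0.58 in D7-A and 0.20 in D7-R against D7 over 1222 genes, beside 0.02 and -0.00434 for 11355 protein-coding genes. Shifts within genes were searched in 1940 genes with at least 200 counts inside a transcript in D7 and 200 outside it in some library, taking the transcript of the largest shift for each gene. For ZNF655 the counts outside the transcript NM_001085367.1 were 1 in D7, 220 in D7-A and 98 in D7-R, while those inside were 243, 228 and 225. For the splicing regulator TIA1 they were 6, 331 and 104 outside NR_147216.1, against 1391, 1514 and 1705 inside. For ASPH they were 2630, 229 and 1624 outside XM_047421785.1, against 5504, 2455 and 4598 inside, and for OPN3 211, 319 and 47 outside NM_001381856.1, against 841, 614 and 941 inside.

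The titles and names of D7-A and D7-R disagree, and exchanged titles are one reading. The planned test, the regional SD in excess of shuffled orders, was 0.0300 in D7-A and 0.0248 in D7-R against D7. By the plan, a larger value in D7-A would go against exchanged titles if the difference exceeded the range over window sizes. The difference of 0.00521 is below the 0.00606 by which window size moved the D7-A value. It is just above the 0.00511 by which window size moved the difference itself. The verdict therefore depends on the spread chosen, and the readings cannot be told apart on this test. The excess was also not scaled for the SD of all log2 ratios, 0.94 in D7-A and 0.68 in D7-R against D7. Some values examined after the results were seen go with exchanged titles, if only a clone selected over many passages carries lasting change. The ratio of observed to shuffled SD was 1.16 in D7-A and 1.30 in D7-R. Chromosome 14 lay below every shuffled order in D7-R against D7 and against D7-A, and no chromosome lay beyond them in D7-A against D7. The difference between FGFR2 last exon transcripts was 4.65% in D7-R, 34.1% in D7-A and 34.0% in D7. Chromosome 22 also lay beyond every shuffled order in D7-R against D7 (0.10), and inside a wider shuffled range in D7-A against D7 (0.11). In D7-R against D7-A its median of 0.04 lay inside the shuffled range, so it does not set these libraries apart. The MAPK list had a median of -1.68 in D7-A, as inhibition of FGF receptors there and not in D7-R would need, but it also lay below its random range in D7-R (-0.39), and immediate early genes were not set apart between D7-R and D7-A by their median of -0.05, though their mean of -0.50 was. A resistant clone kept in the drug could also have a low MAPK list, and cultures of a clone could drift apart, so the titles may or may not be exchanged, and no library was reassigned on these values.

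Chromosome 14 genes were lower in D7-R than in both other libraries. Random placement would put the median against D7 within the shuffled orders, whose lowest value was -0.0595, and the observed -0.27 lies below it. After subtracting the median of genes of the same length and level, -0.26 remained, so a length or level bias is not the whole cause. Each of 4 groups of neighbouring genes along the chromosome was lower, with medians of -0.15 to -0.30 against D7 and -0.22 to -0.41 against D7-A, which is consistent with a lower copy number of the whole chromosome in some or all cells of D7-R. This remains a hypothesis, since DNA was not analysed here, and other clonal differences, such as drift in culture, stay open and untested.

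FGFR2 was 4.26-fold higher in D7-R than in D7, while 17 other detected genes of its region had a median log2 ratio of -0.0414 (SD 0.239), which argues against gain of the region as a whole. More of the same transcripts would keep the 34.0% between canonical and alternative last exon transcripts seen in D7, and the value in D7-R was 4.65%. In the scan of 1940 genes FGFR2 ranked 2, behind ZNF655, in D7-R against D7, with a log2 shift of -4.94 against a 99th percentile of absolute shifts of 0.760. Loss of the canonical last exon without gain of the alternative one cannot be told apart from a switch between them, since the 5' reads that NM_022970 holds and NM_001320654 does not, set against the count of the alternative transcript NM_001144913 as a ratio and not a share of it, came to 32.5% in D7-R, above the 26.4% of D7 and 27.7% of D7-A, where loss alone would leave the ratio and a switch would lower it. A focal gain of FGFR2 with a break near its 3' end, a fusion and a change in splicing may each account for this and stay open, since DNA and reads across junctions were not analysed here.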
